A study of Mus musculus with 8 samples.

How the data were processed

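Total RNA was extracted with Trizol from F4/80-positive tumour-associated macrophages of PyMT mice, and biotinylated cRNA was made with the Affymetrix protocol, per the labels' protocols. The deposited values are log2 signals of 45101 probe sets on 8 arrays, made by the authors with RMA (background correction, quantile normalization and summary over the probes of a probe set), per the submitters' processing notes; the version of RMA, and which arrays were normalized together, are not given in the sources used here. RMA equalises the distributions of the arrays, so a shift shared by most genes would not be seen, and signals near the ends of the scale are compressed. The values were used as deposited, and no scan files were analysed here. No scan date or batch is given in the sources used here.

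Groups were taken from the titles and genotypes: 4 control arrays and 4 E2f3-deleted arrays. The letters in the titles are not shared by the groups, so arrays were not paired. The descriptions name scan files by letters that differ from those of the titles. Grouping by scan file letter was therefore an alternative fixed before the data were examined. It changes the group of 2 arrays, control replicate B and E2f3-deleted replicate F. The largest share of probe sets with an identical value on a pair of arrays was 0.317% and the highest correlation 0.991, so each array was counted once.

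Probe sets were named from the platform's annotation. Of the 45101 probe sets, 64 were controls, 34958 had exactly 1 gene symbol, 932 had several and 9211 had none here. Probe sets with several or no symbols were not named. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, in which 34754 were found and 0 needed updating. That table served only for names and for which genes neighbour each other, and no coordinates are given because the annotation names no genome build. Each of the 18194 genes was represented by the probe set with the highest mean over all arrays. Among the named genes with several probe sets, those of Fam13c, Ehd2, Tmem175, Chaf1b, Wasl, Socs2, Cxcl12, Msmo1, Dnajb1, Lyz1 and Xist did not all have the same direction. Genes whose mean lay under the 40th percentile (log2 6.00) were left out, which left 10916.

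Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with all 8 arrays and no covariate. Every difference is E2f3-deleted minus control on the log2 scale, SE is the limma standard error, and adjusted p-values of single genes are over all genes tested unless stated. E2f3 and lysozyme probe sets were also tested among all probe sets, whatever their level, with 95% confidence intervals. The median difference of all tested genes was −0.03.

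Before the data were examined, 31 gene lists (801 genes, 715 with a probe set) were fixed, covering the E2F family, cell division, macrophage functions, metabolism and markers of other cell types the sorted cells could hold. The 28 lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and an adjusted p under 0.05. With the correlation estimated per list, 0 lists passed. Fry, which tests whether a list's genes move one way on balance, passed 0 (smallest adjusted p 0.189, with 3 at an unadjusted p under 0.05), and its mixed test of change in either direction had a smallest adjusted p of 0.0558. Estimated correlations were 0.808 for mitosis, 0.661 for S phase and 0.933 for endothelial markers. Per-array list medians were compared with exact permutation tests of 70 assignments, two-sided.

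The genes named were fixed by rule: the E2F and pocket protein family with Lyz1 and Lyz2; the 12 largest differences per direction among genes past the threshold with non-overlapping groups, filled up by unadjusted p where fewer pass, which here gave all 24; and up to 4 members of each list with the smallest p. The number of members named, 4 for called lists and 2 for others, was set after the calls were seen. A most abundant member is named for some lists outside this rule, chosen after its values were seen.

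The gene test was checked on simulated arrays made from the 10916 genes' means and spreads, with 200 genes changed. It recovered 58.2% of changes of log2 0.5, 85.1% of 1 and 98.5% of 2, and 14 of its calls (8.00%) were unchanged genes. With no change simulated it called 0. When the mitosis genes alone were lowered by 0.3, camera called 1 list, mitosis; the simulated genes were independent, unlike the real ones.

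Alternatives were the mean of a gene's probe sets, no filter or the 60th percentile, further quantile normalization or median centring, a trended robust prior, array weights, each array left out in turn, every probe set, an adjusted p of 0.1, a fold of at least 1.5, an equal-variance t-test, and the grouping by scan file letter. Chosen after seeing the data were the endothelial median as a covariate and the removal of list members that a marker list of another cell type also holds. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.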

Results

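Gene expression was measured in macrophages taken from the mammary tumours of 80-day-old mice. The mice were of the FVB strain and carried the PyMT transgene, a viral oncogene that gives rise to mammary tumours. Cells bearing F4/80, a macrophage surface protein encoded by Adgre1, were sorted by flow cytometry, and their total RNA was hybridised to Affymetrix arrays. In the control group (4 arrays, replicates B, C, D and G) the E2f3 gene was flanked by recombination sites, with no Cre recombinase. In the E2f3-deleted group (4 arrays, replicates A, E, F and H) the same allele was combined with a Cre recombinase driven from the lysozyme gene, which is active in myeloid cells. The labels do not say whether the arrays came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

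The 8 arrays had closely similar signal distributions, with medians from 5.65 to 5.69 on the log2 scale. E2f3-deleted replicate H stood apart from the others. Its mean correlation with its own group was 0.949, against 0.972 to 0.976 for replicates A, E and F and 0.985 to 0.989 for the controls. The number of arrays limits the precision of every difference given here, and an exact permutation test of 4 against 4 arrays cannot give a two-sided p below 0.0286.

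The comparison of the groups addressed what loss of E2f3 does to gene expression in tumour-associated macrophages. The groups also differ in the presence of Cre, and no group carries Cre without the E2f3 deletion. Loss of E2f3 and the presence of Cre therefore cannot be told apart. E2F3 is a transcription factor that acts on genes of DNA replication and cell division. In E2f3-deleted macrophages the genes of mitosis were lower by a median of −0.33 log2 units, with 30 of 30 measured genes lower, and those of S phase by −0.25, with 35 of 35 lower. Markers of endothelial cells were higher by a median of 1.31. All 16 that passed the filter on mean signal were higher, of 18 with a probe set. Markers of macrophage identity and lysosomes were slightly lower. These list differences passed the test of lists with a preset correlation between genes and none passed when the correlation was estimated from the arrays (smallest adjusted p = 0.744 with an estimated correlation). No single gene passed the threshold when all 8 arrays were used.

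The E2f3 transcript itself differed little between the groups. Its brighter probe set had a log2 signal of 7.67 ± 0.109 in controls and 7.63 ± 0.123 in E2f3-deleted macrophages (SD, n = 4 each), a difference of −0.05 with a standard error of 0.085. The 95% confidence interval ran from −0.24 to 0.15 (limma, adjusted p = 0.865 over all probe sets). The dimmer probe set differed by −0.13, with an interval from −0.33 to 0.06 (limma, adjusted p = 0.613). The labels do not say which part of the gene is deleted, so where these probe sets lie relative to it is unknown and they do not check the labels. Lyz2, the lysozyme gene of macrophages, had a log2 signal of 14.56 ± 0.096 in controls and 14.42 ± 0.085 in E2f3-deleted macrophages, near the top of the scale, and Lyz1 differed by −0.01.

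Of the 13 genes of the E2F and pocket protein family, 11 were lower and 2 higher, with a median difference of −0.10. The activator E2f1 had a difference of −0.23 (SE 0.086, adjusted p = 0.296), E2f2 of −0.22 (SE 0.148) and E2f8, an atypical repressor, of −0.31 (SE 0.155, adjusted p = 0.402). Values nearer to 0 were found for E2f4 (−0.10), E2f5 (−0.01), E2f6 (−0.07), E2f7 (−0.16), Rbl1 (−0.13) and Rbl2 (−0.04), and the dimerisation partner Tfdp1 had −0.18. The other dimerisation partner, Tfdp2, had a value of 0.27 (SE 0.082, adjusted p = 0.244), and Rb1, the retinoblastoma gene, 0.25 (SE 0.123, adjusted p = 0.394). Several of these depended on single arrays. Without replicate H, Rb1 was 0.15 and E2f4 −0.035, without replicate F E2f2 was −0.11, without replicate A Tfdp1 was −0.11 and Rbl1 −0.044, and E2f7 ranged from −0.27 to −0.048, E2f6 from −0.10 to −0.032, E2f5 from −0.046 to 0.036 and Rbl2 from −0.12 to −0.00066. None of the 13 passed the threshold, over all genes tested or adjusted over the list alone, and the list was not called (camera, adjusted p = 0.424, and adjusted p = 0.744 with an estimated correlation).

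Across the 10916 genes tested, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.153. At an unadjusted p under 0.05 there were 1548 genes, 794 higher and 754 lower in E2f3-deleted macrophages, where 545.8 would be expected by chance. That count was 1010 without control replicate B, 1855 without replicate E and, with arrays grouped by scan file letter, 449, below the chance value. A test without moderated variances also passed 0 after adjustment. In 927 genes (8.49%) the 4 values of each group did not overlap, against 2.86% by chance. The count depended on E2f3-deleted replicates E and H. Without replicate E, 60 genes passed (57 higher and 3 lower), and without replicate H, 14 passed, all higher. Fam13c was the only gene in both sets.

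Among the 12 higher genes with the smallest p and no overlap between groups, Fam13c had a log2 signal of 7.12 ± 0.439 in E2f3-deleted macrophages and 5.23 ± 0.305 in controls, a difference of 1.88 (SE 0.234, adjusted p = 0.153). Jam2, a junctional adhesion molecule, was 3.10-fold higher (log2 1.63, SE 0.216, adjusted p = 0.153), and Clec14a, a lectin of endothelial cells, 3.36-fold (log2 1.75, SE 0.284, adjusted p = 0.158). Id3, an inhibitor of helix-loop-helix transcription factors, had a log2 difference of 1.70, Shroom4 of 1.57, Tmem47 of 1.45 and Palmd of 1.15. Smaller values were those of Ehd2 (0.97), Ace, the angiotensin-converting enzyme (0.90), Gask1b (0.76), Tcaf1 (0.35) and Pik3r1, a regulatory subunit of phosphoinositide kinase (0.33). None of these 12 is in the list of endothelial markers, which were higher by a median of 1.31 on the same arrays. This does not show which cells the 12 come from. The list lacks some endothelial genes, Clec14a among them, and only 1 of its 16 tested members had non-overlapping groups.

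The lower genes chosen the same way had smaller differences. Gcnt1, an enzyme of O-glycan branching, had a log2 signal of 7.73 ± 0.085 in E2f3-deleted macrophages and 8.22 ± 0.073 in controls, a difference of −0.49 (SE 0.064, adjusted p = 0.153). Gm11545 had a value of −0.56, Abcc3, a transporter of organic anions, −0.49, and Naglu, a lysosomal glycosidase, −0.42 (SE 0.071, adjusted p = 0.158). Faap24 of the Fanconi anaemia pathway (−0.34), Slc16a6 (−0.31), Tnfrsf11a, the receptor RANK (−0.30), Abr (−0.29), Tmem175 (−0.29), Zfand2a (−0.28), Tcof1 (−0.28) and Dera (−0.26) completed the 12. When replicate E was left out, the 3 lower genes past the threshold, chosen after their values were seen, were Gcnt1 (−0.52), Slc36a2 (−0.59) and Sdf2l1 (−0.68).

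**Figure D1:**
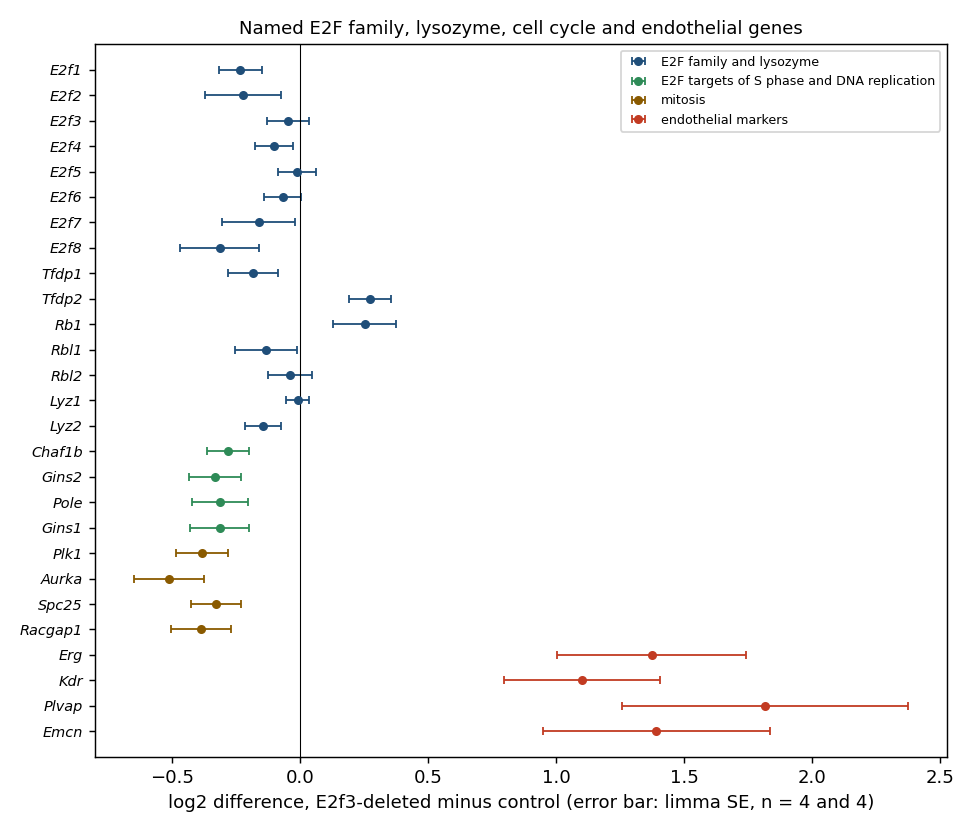
Log2 difference between E2f3-deleted and control macrophages (horizontal axis, log2 units) for the E2F and pocket protein family with the lysozyme genes and for named members of the S phase, mitosis and endothelial lists. Points are differences of means of 4 and 4 arrays and error bars are limma standard errors; the named S phase and mitosis genes lie between −0.51 and −0.28 and the named endothelial genes between 1.10 and 1.82.

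Genes of cell division were lower in E2f3-deleted macrophages. In the mitosis list, 30 of 30 genes were lower, 15 of them at an unadjusted p under 0.05 and 0 after adjustment over all genes or adjusted over the list alone (median −0.33; camera, adjusted p = 5.70e-10, but adjusted p = 0.744 with an estimated correlation). Aurka, a kinase of the mitotic spindle, had a difference of −0.51 (SE 0.137), Plk1, a kinase of mitotic entry, −0.38 (SE 0.101), Racgap1, which acts in cytokinesis, −0.38 (SE 0.117), and Spc25 of the kinetochore −0.33 (SE 0.098). In the list of E2F targets of S phase and DNA replication, 35 of 35 were lower, 12 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median −0.25; camera, adjusted p = 4.80e-08, but adjusted p = 0.744 with an estimated correlation). Its examples were Gins2 (−0.33) and Gins1 (−0.31) of the replicative helicase, the DNA polymerase subunit Pole (−0.31) and the chromatin assembly factor Chaf1b (−0.28). The most abundant members, Mki67 and Pcna, had values of −0.24 and −0.26.

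The per-array medians of the mitosis list, relative to the control mean, were −0.48, −0.12, −0.42 and −0.28 in E2f3-deleted replicates A, E, F and H, and ranged from −0.31 to 0.19 in the controls. The groups overlapped through control replicate C, which lay below E2f3-deleted replicates E and H (exact permutation test, p = 0.0857, 0.320 after adjustment over 28 lists). On the same arrays the endothelial markers were higher by a median of 1.31, the macrophage identity genes lower by −0.10, and the difference between Gapdh signals at the 3′ and 5′ ends, a measure of RNA integrity, was 1.67 ± 0.167 against 1.45 ± 0.0637 in controls (SD, n = 4 each; exact permutation test, p = 0.0571). Both cell division lists lost their call when arrays were grouped by the letter of the scan file instead of that of the title (camera, adjusted p = 0.715 for mitosis and 0.601 for S phase). That grouping exchanges control replicate B and E2f3-deleted replicate F. Both lay nearer to their title groups over genes chosen without them, but with the remaining arrays grouped by title, so this cannot decide between the groupings. With the endothelial median as a covariate, an alternative chosen after seeing the data, the medians were −0.21 for mitosis (adjusted p = 0.0323) and −0.16 for S phase (adjusted p = 0.0443).

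Markers of endothelial cells, which line blood vessels, were higher in 16 of 16 measured genes, 14 of them past the threshold adjusted over the list alone and 0 over all genes tested (median 1.31; camera, adjusted p = 1.49e-10, but adjusted p = 0.744 with an estimated correlation). Plvap, a protein of the endothelial diaphragm, was 3.52-fold higher (log2 1.82, SE 0.558), Emcn 2.62-fold (log2 1.39, SE 0.443), the transcription factor Erg 2.59-fold (log2 1.37, SE 0.369) and the growth factor receptor Kdr 2.15-fold (log2 1.10, SE 0.306). Their levels in the controls were low. None of the 16 lay above the median control signal of all tested genes, 8.72, and the most abundant, Mmrn2, had a log2 signal of 8.61 in controls and 10.40 in E2f3-deleted macrophages. The arrays of the E2f3-deleted group were unlike each other. Replicates A and F had medians of 2.03 and 2.05 above the control mean, replicate E 1.11 and replicate H −0.02, with controls from −0.53 to 0.44 (exact permutation test, p = 0.114). Without replicate H the median was 1.70. The call was lost when arrays were grouped by scan file letter (adjusted p = 0.491).

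Markers of some other cell types also had medians above 0, though none of these lists passed on per-array medians (exact permutation test, p = 0.143 for mast cells and 0.429 each for fibroblasts and epithelium). Markers of mast cells, basophils and eosinophils were higher in 7 of 7 measured genes, 2 of them past the threshold adjusted over the list alone (median 1.31; camera, adjusted p = 0.000428, but adjusted p = 0.744 with an estimated correlation). The list had 15 genes with a probe set, and the filter on mean signal left 7. The mast cell proteases Cpa3 (log2 1.98, SE 1.05) and Cma1 (1.64, SE 0.936) had wide errors, since replicate H had a list median of 3.99, against 0.75, 1.23 and −0.34 in replicates A, E and F; without replicate H they were 0.95 and 0.73. The receptor Kit and the transcription factor Gata2 both had values of 0.85. The list median was 0.64 without replicate H (adjusted p = 0.00538), 0.82 with array weights and 0.26 with dim genes kept, and 3.58 with the endothelial covariate.

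Fibroblast markers were higher in 21 of 22 genes with 0 adjusted over the list alone (median 0.53; camera, adjusted p = 0.000924, but adjusted p = 0.744 with an estimated correlation). Pdgfrb, a receptor of fibroblasts and pericytes, had a difference of 0.92 (SE 0.251), and the matrix genes Postn, Pcolce and Col6a3 had 0.90 (SE 0.530), 0.74 and 0.51. Replicate H had the highest fibroblast median at 1.44, and without it Postn was 0.42, Pcolce 0.35 and Col6a3 0.23. The list median was 0.09 without replicate H (adjusted p = 0.279) and 0.25 without control replicate C (adjusted p = 0.0773), and array weights also ended the call (median 0.17, adjusted p = 0.130). With the endothelial covariate the median was 0.93. The most abundant member, Col1a2, had a log2 signal of 12.29 in controls and 12.40 in E2f3-deleted macrophages.

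Markers of mammary and tumour epithelium were higher in 22 of 26 genes with 0 adjusted over the list alone (median 0.40; camera, adjusted p = 0.000540, but adjusted p = 0.744 with an estimated correlation). Spint2, Esrp1 and Ehf had values of 0.63, 0.57 and 0.54, and the milk protein gene Csn3 0.16. Csn3, the most abundant member, had a log2 signal of 14.17 in controls and 14.32 in E2f3-deleted macrophages, near that of Lyz2 (14.56 in controls). Of the 26 genes, 8 lay above the median control signal of all tested genes, 8.72. The median was 0.29 without E2f3-deleted replicate E, where the call was lost (adjusted p = 0.0600), 0.25 without replicate F, 0.57 without replicate H (adjusted p = 1.06e-07), 0.26, 0.24 and 0.65 without control replicates B, C and D, and turned to −0.18 when arrays were grouped by scan file letter (adjusted p = 0.491) and to −0.23 with the endothelial covariate (adjusted p = 0.522), both without a call.

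Genes of macrophage identity and of the lysosome were lower by small amounts. In the identity list 26 of 27 genes were lower, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median −0.10; camera, adjusted p = 0.00100, but adjusted p = 0.744 with an estimated correlation). The receptor Mertk had a difference of −0.39 (SE 0.128), Cd68 −0.29 (SE 0.095), Sirpa −0.19 and Adgre1, which encodes the protein used for sorting, −0.18 (SE 0.061). The 8 identity genes with a mean log2 signal under 12 had a median of −0.22, against −0.10 for the whole list, whose other members lie nearer to the top of the scale. The lysosome list was lower in 27 of 29 genes, with 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median −0.15; camera, adjusted p = 7.11e-05, but adjusted p = 0.744 with an estimated correlation). Lgmn had a value of −0.29, Gusb and Glb1 −0.20 each, and Ctsa −0.19. The lysosome medians of the 4 E2f3-deleted arrays, −0.18 to −0.10, lay below those of the controls, −0.05 to 0.08 (exact permutation test, p = 0.0286, the smallest possible, 0.320 adjusted). On these arrays the endothelial median was 1.31 higher and the Gapdh 3′ minus 5′ difference was 1.67 against 1.45. Replicate H, at −0.02 for endothelial markers, had the lowest lysosome and identity medians of the 8 arrays, −0.18 and −0.14. The difference of per-array lysosome medians was −0.136 (SE 0.0347), and −0.156 (SE 0.0522) with the endothelial median as a covariate. Its slope on the endothelial median was 0.015 (SE 0.029). Grouping by scan file letter ended the call of the identity list (adjusted p = 0.610) and lowered the size of the lysosome median to −0.098. The endothelial covariate also ended the identity call (adjusted p = 0.0546) though the median, −0.11, was no smaller: the difference of per-array medians went from −0.081 (SE 0.0306) to −0.095 (SE 0.0466), with a wider error.

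Hypoxia and glycolysis genes were lower in 23 of 27, 10 of them at an unadjusted p under 0.05 and 0 adjusted over the list alone (median −0.25; camera, adjusted p = 0.000227, but adjusted p = 0.744 with an estimated correlation). Ankrd37, a target of hypoxia-inducible factor, had a value of −0.88 (SE 0.257), Mxi1 −0.32, and the glycolytic enzymes Pfkfb3 and Hk2 −0.31 and −0.28. Replicate A had the lowest median, −0.51. Every E2f3-deleted array lay below every control on this list (exact permutation test, p = 0.0286, 0.320 adjusted), with the endothelial median 1.31 higher. The margin was small, −0.125 in E2f3-deleted replicate E against −0.117 in control replicate B. The difference of per-array medians was −0.26 (SE 0.124), and −0.24 (SE 0.192) with the endothelial median as a covariate. The Gapdh 3′ minus 5′ difference was 1.67 against 1.45 in controls (exact permutation test, p = 0.0571) and 1.87 in replicate A, the highest of the 8 arrays. Gapdh is itself the most abundant member of the list (−0.20). Without control replicate D the median was −0.17 and the call was lost (adjusted p = 0.0614).

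Interferon-stimulated genes were higher in 23 of 30, with 0 adjusted over the list alone (median 0.15; camera, adjusted p = 0.00341, but adjusted p = 0.744 with an estimated correlation). On per-array medians the groups differed by only 0.076 (exact permutation test, p = 0.657). The guanylate-binding protein gene Gbp2 had a value of 0.58 (SE 0.190), the RNA sensor Ifih1 0.28, and the GTPase genes Ifi47 and Igtp 0.25 and 0.14 (0.13 and 0.080 without replicate H). Replicate H, with the highest mast cell and fibroblast medians, had an interferon median of 0.41 and replicate A one of −0.31. Without replicate H the list median was 0.02 (adjusted p = 0.283), without replicate E 0.11 (adjusted p = 0.0600), without replicate A 0.26 and without control replicate B 0.09. Array weights gave 0.066 (adjusted p = 0.0172) and the endothelial covariate 0.38 (adjusted p = 1.47e-07), and with arrays grouped by scan file letter the call was lost (adjusted p = 0.167).

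**Figure D2:**
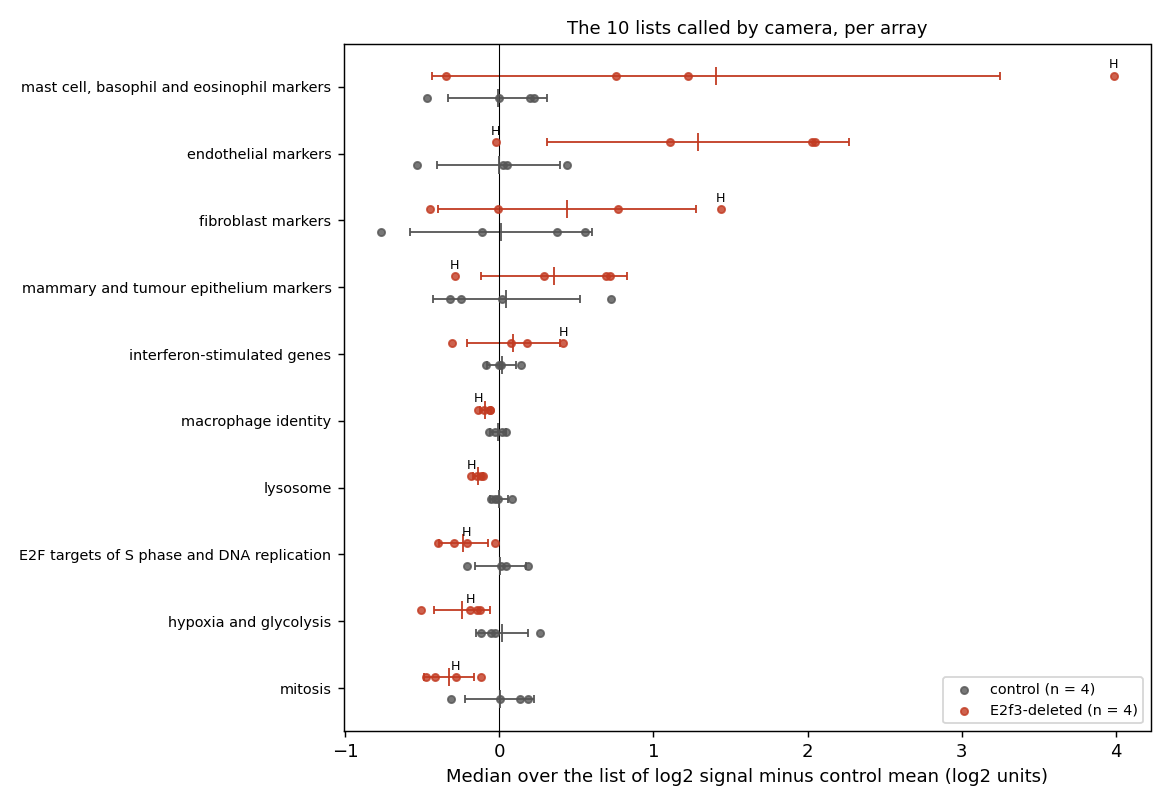
Median log2 signal of each called list relative to the control mean (horizontal axis, log2 units) in each control and E2f3-deleted array. Points are arrays, bars mark the mean and SD of 4 arrays, and replicate H is lettered; it lies at −0.02 for endothelial markers and at 3.99 for mast cell, basophil and eosinophil markers.

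Several functional lists of macrophages were not called. The actin cytoskeleton and migration list had a median of −0.08, with 37 of 53 genes lower, among them the exchange factor Vav1 (−0.23), while Wasl, an activator of actin branching, had 0.32 (camera, adjusted p = 0.386). Alternative activation had a median of −0.23 with 22 of 26 lower (adjusted p = 0.346), Trem2 at −0.35 and Socs2 at 0.57, but without replicate H the median was −0.0022 with 13 of 26 lower. That list was called with the endothelial covariate (median −0.65, adjusted p = 0.000270) and with arrays grouped by scan file letter (−0.33, adjusted p = 0.00199). Replicate H, which that covariate sets apart from the other E2f3-deleted arrays, had a median of −0.77 on this list. Inflammatory activation had a median of −0.08 (adjusted p = 0.577), with Il1rn at −0.52 (SE 0.373; −0.24 without replicate H) and Il1b at 0.17 (0.085 without control replicate G), and ranged from −0.23 without control replicate C to 0.022 without replicate E as each array was left out. Antigen presentation genes had a median of 0.04 with 14 of 18 higher (adjusted p = 0.127), H2-Aa at 0.11 and Tapbp at 0.10 (0.049 without replicate H), and passed without control replicate B (adjusted p = 0.0427), with genes under the 60th percentile left out (0.0308), with the endothelial covariate (0.0370) and with arrays grouped by scan file letter (0.00299). Their median ranged from 0.015 without control replicate D to 0.080 without control replicate B as each array was left out. The calls given here under alternatives rest on the preset correlation of 0.01. Estimated correlations were 0.478 for alternative activation and 0.056 for antigen presentation, and 0 lists passed with estimated correlations on all arrays.

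The list of tumour-promoting macrophage factors had a median of −0.04 and a mean of 0.18, and camera placed it higher (adjusted p = 0.466). The chemokine gene Cxcl12 (log2 1.99, SE 0.399, adjusted p = 0.163) and the lymphatic growth factor gene Vegfc (1.63, SE 0.394) were its members with the smallest p, and 1 of 35 members passed adjusted over the list alone. With each array left out the median ranged from −0.052 to 0.0015. Lipid uptake and efflux had a median of −0.12, a mean of 0.01 and a direction of lower by camera (adjusted p = 0.563), and the median ranged from −0.24 without control replicate B to −0.026 without control replicate C. The fatty acid-binding protein gene Fabp4 was 4.01-fold higher (SE 0.528 on the log2 scale) and the receptor gene Lrp1 had −0.30. These values stood beside the endothelial median of 1.31, and Tek is a member of both the endothelial and the tumour-promoting lists.

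Median differences of the remaining functional lists were −0.07 for cholesterol synthesis (14 of 20 lower, adjusted p = 0.419, Tm7sf2 −0.33, Msmo1 −0.18, or −0.11 without replicate H) and −0.03 for oxidative phosphorylation (26 of 41 lower, adjusted p = 0.577, Ndufs1 −0.11, Sdhb −0.11). Targets of p53 had a median of −0.02 and a mean of 0.05 (camera higher, adjusted p = 0.682), with Mdm2 at −0.21 and Trp53inp1 at 0.45 (0.26 without replicate H). Immediate early and dissociation stress genes had a median of −0.03, though camera placed them higher (adjusted p = 0.923), with Rhob at −0.17 and Dnajb1 at 0.15 (0.061 without replicate E). Ribosomal protein genes had a median of 0.02 and a mean of −0.01 (camera higher, adjusted p = 0.484), with Rps25 at −0.42 and Rps4x at 0.06. Leaving out control replicate C brought cholesterol synthesis past the threshold (median −0.12, adjusted p = 0.0382), and its median was −0.033 without control replicate G. With each array left out, the medians ranged from −0.047 to −0.0046 for oxidative phosphorylation, from −0.033 to 0.018 for p53 targets, from −0.10 without replicate A to 0.032 without replicate E for immediate early genes and from −0.012 to 0.027 for ribosomal protein genes, so the sign of the last 3 was not stable.

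Among other white blood cells, B cell markers had a median of −0.55 with 5 of 7 lower (camera, adjusted p = 0.150), with Bank1 at −0.55 (SE 0.162) and Cd22 at −0.36 (−0.23 without replicate E). Replicate H had the lowest B cell median, −1.61, and the list passed when control replicate D was left out (adjusted p = 0.0480) or dim genes were kept (adjusted p = 0.0421). T and NK cell markers had a median of −0.11 (5 of 7 lower, adjusted p = 0.657, Cd4 −0.24, Cd3e −0.11) and 0.03 without replicate H. Neutrophil markers had 0.21 (5 of 8 higher, adjusted p = 0.682, Lcn2 0.34, Csf3r −0.19) and dendritic cell markers 0.08 (8 of 13 higher, adjusted p = 0.494, Cd24a 0.45, Itgax −0.31). Monocyte markers had a median of −0.01 and a mean of 0.23 (camera higher, adjusted p = 0.419), with Ace at 0.90 past the threshold adjusted over the list alone and Hp at 1.38 (SE 0.945; 0.51 without replicate F). Adipocyte markers had 0.03 (4 of 5 higher, adjusted p = 0.484), with Fabp4 past the threshold adjusted over the list alone and Lipe at −0.22. Without replicate H Itgax was −0.17, without control replicate C Lcn2 was 0.17, without replicate F Csf3r was −0.30 and without control replicate B Cd3e was −0.071. Leaving out 1 array could turn the sign of the neutrophil (−0.034 to 0.31), dendritic cell (−0.043 to 0.19), monocyte (−0.076 to 0.079) and adipocyte (−0.061 to 0.22) medians.

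For 3 lists under 5 members were measured and no list test was run. The erythroid genes Alas2 and Epor had values of −0.62 and −0.20, the muscle enzyme gene Eno3 −0.32, and Xist, expressed from the inactive X chromosome, 0.03, with log2 signals of 11.81 in controls and 11.85 in E2f3-deleted macrophages. These values depended on single arrays: Epor was −0.055 without replicate H and −0.014 without control replicate C, Alas2 −0.38 without control replicate B, Eno3 −0.14 without control replicate G, and Xist ranged from −0.11 to 0.13.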

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

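A value far from the other 3 of its group was found in 19 of 294 groups of 4 arrays tested (gap to the nearest array over the group's range above Dixon's critical value), where 14.7 would be expected by chance at 1 in 20. These were spread over all 8 arrays, from 1 each in E2f3-deleted replicates E and F to 5 in control replicate D, and no explanation is offered for them.

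E2f3-deleted replicate H had a mean correlation with its own group of 0.9488, below the nearest at 0.9723. It also had the lowest adipocyte median of its group at −0.298 (nearest 0.2459) and the highest Lrp1 signal at 11.73. Replicate A had the lowest hypoxia and glycolysis median at −0.5093 (nearest −0.1889) and the highest T and NK cell median at −0.0241. Replicate E had the highest Gusb signal at 12.74 and replicate F the highest Csf3r signal at 9.07, all on the log2 scale.

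Among controls, replicate D had the lowest log2 signals of the mast cell proteases Cpa3 at 6.56 (nearest 8.13) and Cma1 at 6.30 (nearest 7.44), the lowest of Gcnt1 at 8.11 and Sdhb at 12.03, and the highest of Tcaf1 at 7.96. Replicate B had the lowest of Ace at 6.93 and Ifi47 at 11.36 and the highest of Dera at 9.77. Replicate C had the highest alternative activation median at 0.445 (nearest −0.0654) and the lowest Rps4x signal at 14.08. Replicate G had the highest Tm7sf2 signal at 8.01 and the highest Eno3 signal at 8.22.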

How the results depend on the processing

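The alternatives were planned before the data were examined except the endothelial covariate and the removal of shared list members, which were chosen after seeing the data. Among E2f3-deleted arrays the endothelial median was −0.02 in replicate H and 1.11 to 2.05 in the others, so that covariate also carries what is particular to replicate H. The alternative activation, mast cell, fibroblast and interferon medians were −0.65, 3.58, 0.93 and 0.38 with it, but −0.0022, 0.64, 0.09 and 0.02 without replicate H. The count of genes passing was 0 under every alternative, in limma and in a t-test, but the arrays left out in turn, where it ranged from 0 to 60 (60 without E2f3-deleted replicate E, 14 without replicate H). Fewer arrays enter those fits, and the cause was not tested. The smallest adjusted p over settings with 0 genes ranged from 0.0785 with array weights to 0.893 with grouping by scan file letter, where 449 genes had an unadjusted p under 0.05. Of 10 lists called, 0 passed with an estimated correlation and 0 with fry, and 8 to 11 passed under the other alternatives. Grouping by scan file letter ended the calls of the mitosis, S phase, macrophage identity, interferon, endothelial and epithelium lists and added 4 others (alternative activation −0.33, antigen presentation 0.09, lipid uptake and efflux −0.10, immediate early 0.07).

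The E2f3 difference was 0.021 with grouping by scan file letter and from −0.10 to 0.0052 with each array left out. The epithelium median was −0.18 with grouping by scan file letter and −0.23 with the endothelial covariate. Of 2034 values of named genes, 2000 kept direction and side of the threshold, 12 passed it and 22 changed sign. With grouping by scan file letter these were Alas2 0.084, E2f2 0.15, E2f3 0.021, E2f6 0.028, E2f8 0.038, Ehf −0.088, Esrp1 −0.016, Hp −0.85 and Rbl2 0.015. With the endothelial covariate they were E2f3 0.030, Rbl1 0.053, Rbl2 0.051 and Xist −0.046. Array weights gave E2f5 0.022, and the mean of probe sets Xist −0.066. With each array left out the ranges were −0.046 to 0.036 for E2f5, −0.022 to 0.0091 for Lyz1 and −0.11 to 0.13 for Xist. Of 115 named genes, 34 moved by over 1.5 times or changed sign with 1 array left out. The cause of these changes was not tested. Dim genes limit what arrays can show: without the filter 2157 genes had an unadjusted p under 0.05, and 0 passed.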

Other observations

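Further lists were written after the main results were seen and before their own values were looked at as lists, though single members had been seen. Of 12 genes of pericytes and smooth muscle, the cells that wrap blood vessels, 11 were higher in E2f3-deleted macrophages, with a median log2 difference of 0.64. At an unadjusted p under 0.05 there were 4 higher genes and 1 lower. Gucy1b1 had a difference of 1.64 (SE 0.325, adjusted p = 0.160), Vtn 1.12 (SE 0.405), Abcc9 0.78 (SE 0.209) and Kcnj8 0.77 (SE 0.175), and the lower gene was Cspg4 at −0.54. Replicates A and F had list medians of 1.26 and 1.29 above the control mean, replicate E 0.28 and replicate H −0.17, with controls from −0.18 to 0.18. The list median was 0.91 without replicate H and 0.27 without replicate F, the extremes as each array was left out. Of the 14 genes that passed without replicate H, those with the smallest p were Dkkl1 (1.12) and Atp6v1b1 (1.23). Others, chosen after their values were seen, were Cavin1 (1.04) and Cavin2 (1.86) of caveolae, the endothelial receptor Tie1 (1.43) and the apelin receptor Aplnr (1.83). Only 1 member of the endothelial list was among these 14, and 0 were among the 60 genes that passed without replicate E. Of those that passed without replicate E, the genes with the smallest p were Ntn4 (1.47), Il1r1 (1.08), Fbln5 (1.80) and Fzd4 (1.45), all higher.

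The tests of chance over splits, except that of genes at an adjusted p, the tests of cell division and the test of endothelial RNA were chosen after the results they bear on were seen. For genes at an adjusted p under 0.05, the real split of the 8 arrays into 4 and 4 gave 0 (highest other 5), so all 35 of 35 splits gave as many by construction and the count says nothing about chance. At an unadjusted p under 0.05 only 1 of 35 splits, the real one, gave as many as 1548 (highest other 1086). That is the most extreme result 35 splits can give, for a measure chosen after the count was seen. It makes a chance split less likely for that count, as the arrays are labelled by title, but does not exclude it. With arrays grouped by scan file letter the count was 449. For the lists called, 16 of 35 splits gave as many as the real 10 (highest other 13), so chance cannot be excluded, and the arrays have a structure that calls lists under many splits.

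Since no gene passed, explanations for differing genes were tested on those with the smallest unadjusted p. DNA of another strain around the Cre insertion would raise their share near Lyz2, but 28 of 175 neighbours had an unadjusted p under 0.05 against 14.2% of all genes, a ratio of 1.13 under the bound of 1.5 set before (Fisher's exact test, one-sided, p = 0.273). A swap of labels between the groups needs an array of each group out of place, and over 100 genes chosen without each array 0 controls were nearer to the E2f3-deleted group. The bound first set, every array nearer to its own group, was not met. The reading that a swap needs an array of each group was adopted afterwards. E2f3-deleted replicates E and H were nearer to the controls, and control replicate D had a small margin (distance 5.37 to its own group, 6.57 to the other). An array labelled E2f3-deleted could thus lie nearer to the controls, so this test cannot exclude a swap, and a single wrong label stays open. Control replicate B and E2f3-deleted replicate F, which trade groups by scan file letter, lay nearer to their title groups. Their distances were 3.70 and 3.67, against 11.33 and 9.77 to the other group. The genes were chosen with the remaining arrays grouped by title. Replicates B and F also had the lowest and highest endothelial medians of the 8 arrays (−0.53 and 2.05). These distances therefore cannot decide between the groupings. A different share of epithelial tumour cells also stays open. A sort on F4/80 should remove them, but the milk protein gene Csn3 had a log2 signal of 14.17 in controls and 14.32 in E2f3-deleted macrophages. The epithelium median was 0.40, between the bounds set before. It was 0.57 without replicate H and 0.65 without control replicate D, both past the bound of 0.5 for this cause. However, it was 0.24 without control replicate C, −0.23 with the endothelial covariate and −0.18 with arrays grouped by scan file letter.

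The cell division lists were lower by a mean of their medians of −0.29. In 3 of 35 splits this was as far from 0 (highest other 0.376 against 0.289 in size), so chance cannot be excluded. A lower share of macrophages with all other cell types raised alike would move endothelial and white blood cell markers together. The endothelial median lay above that of 22 T and NK, B cell and neutrophil markers by 1.41 (SE 0.495). In 3 E2f3-deleted arrays this excess was above all controls. It argues against a like rise of these white blood cells, though the comparison was chosen after the main results were seen. Mast cell, fibroblast and epithelium markers, left out of it, had medians of 1.31, 0.53 and 0.40. Dilution by endothelial RNA may still contribute, since macrophage identity genes lay above mitosis genes by only 0.25 (SE 0.154), 8 identity genes under a log2 signal of 12 had a median of −0.22, and with the endothelial covariate mitosis went from −0.33 to −0.21 and S phase from −0.25 to −0.16, both still called; the per-array mitosis difference with it was −0.22 (SE 0.202), too wide to decide. RNA quality is open as well: with the Gapdh 3′ minus 5′ difference as a covariate the value was −0.13 (SE 0.162). Although the ranges of that difference overlap between groups, the bound first set for excluding it, the cell division medians overlap too. The same measure for beta-actin differed less, 1.02 ± 0.141 against 0.89 ± 0.0702 in controls (SD, exact permutation test, p = 0.171). Loss of E2f3, the presence of Cre and RNA quality cannot be told apart here.

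The endothelial markers were higher by a median of 1.31, and 2 of 35 splits gave as large a median (highest other 1.52), so chance cannot be excluded. RNA of endothelial cells among the sorted cells is a candidate source, though a sort on F4/80 should remove them. In a second endothelial list of 22 genes, 15 passed the filter on mean signal. Of these, 13 were higher, with Cd34 at 1.14, Gpihbp1 at 1.44 and Podxl at 1.44. The median of 0.64 lay just under the bound of 0.654, a fixed share of the earlier list's median. It ranged from 0.46 without replicate A to 0.77 without replicate E. Without replicate H, the form in which the test was first written, 14 of 15 were higher and the median of 0.68 was under its bound of 0.852. The markers were dim in controls, the most abundant being Mmrn2 at 8.61 and Kdr at 8.58, 1 of the 16 is also in another list, and a change of expression within macrophages that follows E2f3 loss was not tested and stays open.

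A hypothesis was that the groups were sampled at different hours, from low values of the clock outputs Dbp (−0.41, SE 0.126, adjusted p = 0.253) and Tef (−0.34, SE 0.0921, adjusted p = 0.218), both noticed in the data. The 5 measured clock genes in phase with Dbp had a median of −0.18, with 4 of 5 lower, Nr1d1 at −0.35 and the largest difference of the 5 in the other direction (Hlf, 0.44, SE 0.230), and the 3 measured genes in antiphase a median of 0.01. Hlf depended on replicate H: without it Hlf was 0.23, smaller in size than Per3 (−0.32) and Nr1d1 (−0.28). The median of −0.18 lies between the bounds set before, −0.2 and −0.1. Without replicate H the medians were −0.21 and 0.050, which would meet the bounds for this cause, but without replicate A the first was −0.078, past the bound against it, so these genes cannot decide.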
